A study of Mus musculus with 13 samples.

How the data were processed

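Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on neural stem and progenitor cells grown as floating spheres (neurospheres). The cells came from the cortex and ganglionic eminences of mouse embryos at embryonic day 14.5 and were taken at passage 5, day 3 of culture. The antibodies recognised acetylated lysine 14 of histone H3 (H3K14ac) or the lysine acetyltransferase KAT7, also called HBO1, which acetylates that residue. Per the labels, 13 libraries were made: 4 H3K14ac libraries from Kat7-intact cells, 3 H3K14ac libraries from Kat7-deleted cells, 3 KAT7 libraries from Kat7-intact cells, 1 KAT7 library from Kat7-deleted cells and 1 IgG library for each experiment. Both genotypes carried a Cre transgene driven by nestin (Nes) regulatory sequence.

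The values used were the authors' deposited table of genomic regions. Per the file headers it holds, for each region, a read count and an RPKM value (reads scaled to region length and to the column's read total) for 1 merged H3K14ac column and 1 merged KAT7 column. Per the submitters' processing notes the genome build was mm10 and the tools included Bowtie2, SAMtools, Picard, deepTools and featureCounts; their versions, roles and order are not given in the sources used here. Which libraries and which Kat7 genotype entered each merged column, and what the abbreviations SC and gc in the column names stand for, is also not given in the sources used here. The counts are whole numbers, but a correction applied to the alignments before counting cannot be excluded. The deposited RPKM equals the count divided by the region's end minus its start and by 1 read total per column, 141734087 reads for H3K14ac and 134111848 for KAT7; this held for 100% of regions with a count, within a relative tolerance of 1e-06. What those totals count is not stated. No column of a single library, of a genotype or of IgG was used here.

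The tests planned before the data were examined compared Kat7-deleted with Kat7-intact libraries, and each antibody with IgG, per region with limma, with gene-set and permutation tests on the same libraries. They need values per library and could not be run on 2 merged columns. The 1 planned result that merged columns allow is the rank correlation of KAT7 with H3K14ac across regions, here without IgG. The gene lists, the genes always named and the minimum RPKM were also fixed before the data were examined. Everything else was chosen after the columns or the first values had been seen: the region classes compared, the expression classes, the profile around the transcription start site (TSS), the matched random lists, the ratio of KAT7 to H3K14ac and the exclusions described next.

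The table holds 240814 regions in 12 classes, named by the authors. On the minus strand, 10290 promoter and 10290 post-TES entries (TES, transcription end site) have a length of -1999 bases and 0 reads, so promoters and post-TES windows of 2001 bases were used for plus-strand genes alone. Regions that share bases with another region of their class, 29067 in all, were left out, since a read falling in both was not counted in either: 13518 entries without a base of their own held 0 reads. The 45 mitochondrial entries and 370 regions above 5 RPKM in either column were set apart. Chromosomes X and Y were set apart after a first run had shown them near 0.5 of the autosomal level; genes named on X are given with their chromosome. Regions with a mean of both RPKM values below 0.1 were removed, which took out 720 of 184983 regions and left 184263. Gene symbols came from the RefSeq gene table of assembly GRCm38.p6 by gene identifier, for names alone, and were found for 96.7% of 20689 genes. The file marks 1034 genes as Top and 1035 as Bottom in expression, 5% of genes each, and the remainder as Other. The expression data behind these marks are not given in the sources used here.

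The level of a group of regions was its summed count over its summed length and the column's read total, with an exact Poisson 95% interval. Ratios of KAT7 to H3K14ac, and of one group to another within a column, carry exact binomial 95% intervals. Reads are not independent molecules and the merged columns carry no replicates, so all intervals cover counting error only, and no p-value is given. A CpG island was assigned to a gene when it contains that gene's TSS; 12881 islands near a TSS were used, 8899 contain a TSS and 7926 contain exactly 1. The class comparisons at islands used the latter. The TSS profile used 54377 Enh and IS elements of at most 160 bases by the distance of their middle to the nearest TSS. A read that only reaches over a region's edge is counted in full, which raises the RPKM of short regions, so classes were compared within bands of length.

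There were 37 gene lists. For each list with at least 5 measured members, the median RPKM of its members was placed among the medians of 10000 random lists of the same size, matched on expression class and on 20 bins of length, and called outside when beyond the central 95% of random medians. The number of length bins was changed from 5 to 20 after the first results, because olfactory receptor genes, which are short, had come out above range for both antibodies; with 20 bins their H3K14ac was still above it and their KAT7 was not. Expression was matched by class alone, and the middle class holds 18620 of 20689 genes, so differences in expression within it were not matched. Base makeup was not matched. Lists share members and neighbouring genes, so the calls are not independent. The rank correlation was set beside the value from counts simulated with 1 constant density per column plus reads reaching over the edges, to show what length and counting noise alone give. A first version of that simulation used a fit with a negative intercept and was replaced.

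The genes named by rule were Kat7, its complex subunits, Sox2, Nes, Pax6, Dcx, Tubb3, Gfap, Olig2, Mcm2, Actb and Gapdh, and from every list the 2 members of highest mean RPKM. Added after the data were seen were, for islands and for gene bodies, the 8 genes with the highest lower interval bound for each antibody, and the 8 highest and 8 lowest in KAT7 over H3K14ac by interval bound. Predicted genes, pseudogenes and clone names were left out of these. The parts of the fixed rule that need called regions could not be applied.

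The steps were checked on simulated counts with known answers. These counts held counting error alone around a level shared by both columns. The check therefore does not cover variation between libraries or differences in sequence bias between the columns. Among 8899 simulated islands, the interval of KAT7 over H3K14ac excluded 1 for 59.7% of islands with a true ratio of 1.5, 92.5% with 2, 73.8% with 0.5 and 3.89% of unchanged ones; among 15774 gene bodies the shares were 98.5%, 97.0%, 100% and 4.58%. Random lists of 15 members raised by a factor of 1.2 were called above in 49 of 100 trials at islands and in 100 of 100 at gene bodies, and unchanged lists were called outside in 2 and 3 of 100. Alternatives were run for the minimum RPKM, the sex chromosomes, medians in place of sums, overlapping regions, island length, islands with several TSSs, the kind of short element, CpG islands and the length bins. Scripts used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.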

Results

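H3K14ac and KAT7 were measured by ChIP-seq in mouse neural stem and progenitor cells cultured as neurospheres, with 7 H3K14ac libraries, 4 KAT7 libraries and 2 IgG libraries named in the labels. The design asks where KAT7 binds and how H3K14ac differs between Kat7-intact and Kat7-deleted cells. The deposited values are the authors' merged values, 1 for each antibody, with read totals of 141734087 for H3K14ac and 134111848 for KAT7. No comparison of genotypes and none with IgG was analysed here, and background reads could not be subtracted. What follows compares the merged values between genes and regions (mm10 coordinates). Values are RPKM with a 95% counting interval in parentheses, and there are no replicates behind them. The antibodies share no common scale, so a KAT7 to H3K14ac ratio above or below 1 compares scaled reads, not occupancy with acetylation.

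Kat7 itself (gene 217127, chromosome 11, 95271853 to 95310246) encodes the acetyltransferase under study. The CpG island at its TSS (95309551 to 95310258) had an H3K14ac value of 0.788 (0.624 to 0.983) and a lower KAT7 value of 0.432 (0.310 to 0.587). Brpf1 (chromosome 6, 113306583 to 113307700), a scaffold subunit of KAT7 and related complexes, had the same order at its island, 0.752 (0.623 to 0.899) against 0.441 (0.341 to 0.561). Other subunits had ratios above 1. Ing5, which reads methylated H3, had a KAT7 to H3K14ac ratio of 2.30 (1.38 to 3.94) at its island (chromosome 1, 93803477 to 93804391), Jade2 had 1.82 (1.34 to 2.49) and Brpf3 had 1.65 (1.13 to 2.42). Meaf6, with 1.51 (0.961 to 2.4), could not be told from 1. Over gene bodies, KAT7 was above H3K14ac at Kat7 (ratio 1.19, 1.12 to 1.27), Jade2 (1.19, 1.12 to 1.26), Brpf1 (1.2, 1.09 to 1.32), Ing4 (1.28, 1.13 to 1.46), Ing5 (1.24, 1.13 to 1.36), Meaf6 (1.13, 1.04 to 1.23), Brpf3 (1.11, 1.04 to 1.19), Brd1 (1.12, 1.06 to 1.19) and Jade1 (1.07, 1.02 to 1.12). Jade3, on chromosome X, had 1.00 (0.938 to 1.07) and could not be told from 1. The median ratio of all gene bodies was 1.05, which the intervals of Jade1, Brpf3 and Meaf6 include. Gene body medians, 0.381 for H3K14ac and 0.399 for KAT7, were close to those of the file's pseudogenes, 0.390 and 0.396. The file's H3K9me3 domains lay there too, with medians of 0.393 and 0.395 in its set 1 and 0.392 and 0.392 in its set 2. Without IgG, how much of a gene body value is background is not known, here or in the gene body comparisons below. Because the merged columns do not separate genotypes, the Kat7 values do not check the deletion.

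Nes, Olig2, Olig1, Spry4 and Mir9-1 were among the 8 genes whose TSS islands had most KAT7 by lower interval bound, a ranking added after the data were seen. Of these, Nes and Olig2 belong to the list of neural stem and radial glia genes, Olig1 to that of the oligodendrocyte lineage and Spry4 to that of FGF and EGF signalling. Nes (gene 18008), which encodes the intermediate filament nestin of neural progenitors, had 1.52 (1.32 to 1.74) for H3K14ac and 1.69 (1.47 to 1.93) for KAT7 at the island over its TSS (chromosome 3, 87971020 to 87971963). Reads from the nestin-driven transgene cannot be told apart from those of the gene where the sequences are shared. Olig2 (gene 50913, chromosome 16, 91225320 to 91227642), a transcription factor of ventral progenitors and the oligodendrocyte lineage, had 0.784 (0.691 to 0.886) for H3K14ac and 1.28 (1.16 to 1.41) for KAT7, and its neighbour Olig1 (91269577 to 91271739) had 1.09 (0.979 to 1.22) and 1.15 (1.03 to 1.28). Spry4 (chromosome 18, 38600646 to 38601554), a feedback inhibitor of receptor tyrosine kinase signalling, had 1.31 (1.12 to 1.53) and 1.36 (1.16 to 1.59), and Spry2 had 0.830 (0.713 to 0.959) and 0.987 (0.857 to 1.13). The island of the microRNA gene Mir9-1 (chromosome 3, 88214461 to 88215599), which is expressed in neural progenitors, had 0.874 (0.736 to 1.03) and 1.34 (1.17 to 1.54). Sox2, a core transcription factor of neural stem cells, had 0.631 (0.552 to 0.719) and 0.776 (0.685 to 0.875) at its island (chromosome 3, 34648829 to 34651366). The others of the 8 were Tsc22d2, with 0.614 (0.536 to 0.700) for H3K14ac and 1.1 (0.988 to 1.21) for KAT7, Mir3093, which shares the Mir9-1 island, and Hjurp, a centromere protein gene, with 2.83 (2.45 to 3.25) and 2.55 (2.18 to 2.97). Hjurp was high in both columns alike, and whether its sequence has further copies was not checked. For comparison, the median of CpG islands near a TSS was 0.461 for H3K14ac and 0.491 for KAT7.

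Some islands with much H3K14ac had a lower KAT7 value, although KAT7 at Rpl17, Bcan, Disc1, Ring1 and Mcm3 was still above the island median of 0.491. Rpl17, a ribosomal protein gene (chromosome 18, 75000427 to 75000996), had 1.87 (1.59 to 2.20) for H3K14ac and 0.668 (0.498 to 0.879) for KAT7. Bcan, which encodes the brain proteoglycan brevican (chromosome 3, 87999753 to 88000469), had 1.56 (1.32 to 1.82) and 0.844 (0.670 to 1.05). Disc1 had 1.62 (1.39 to 1.88) and 0.801 (0.636 to 0.996), Ring1, a Polycomb ubiquitin ligase gene, 1.40 (1.22 to 1.61) and 0.748 (0.610 to 0.907), and Mcm3, a replicative helicase subunit gene, 1.35 (1.06 to 1.68) and 0.565 (0.384 to 0.802). The ratios of KAT7 to H3K14ac with the lowest upper bound were at Cirbp, a cold-induced RNA-binding protein gene, with 0.217 (0.143 to 0.319), Unc119 with 0.236 (0.140 to 0.382), Adamts3 with 0.276 (0.167 to 0.441), Tmem181a with 0.342 (0.249 to 0.464) and Mgat3 with 0.334 (0.236 to 0.464), in the order of their upper bound. Tmem181a has a pseudogene relative, so its value is uncertain. Those with the highest lower bound were at Zfp384, a zinc-finger factor gene, with 14.0 (5.69 to 44.4) from 5 H3K14ac and 66 KAT7 reads, Pheta1 with 9.93 (3.97 to 32.0), Rbm15b, an RNA methylation cofactor gene, with 4.87 (3.48 to 6.94), Socs6 with 6.34 (3.32 to 13.3) and Rasa2 with 6.34 (3.22 to 13.9). Across 9876 genes with an island at the TSS, the interval of the ratio lay above 1 for 1448 and below 1 for 820, and the median ratio was 1.06. These extremes were picked from all genes by their interval, so their sizes are overstated by chance.

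Across gene bodies the KAT7 to H3K14ac ratio had its highest lower bounds at the microRNA gene Mir200c, with 10.0 (2.42 to 88.9) from 2 H3K14ac and 19 KAT7 reads, and at Rbm15b, with 2.8 (2.25 to 3.5). Of the others in the highest 8, Pou3f3, a POU transcription factor of neural progenitors (chromosome 1, 42697146 to 42700210), had 0.9 (0.811 to 0.997) for KAT7 and 0.368 (0.314 to 0.430) for H3K14ac. Zic1 (chromosome 9, 91360345 to 91365799) and Zic2 (chromosome 14, 122475384 to 122480328), zinc-finger factors of dorsal neural patterning, had KAT7 values of 0.822 (0.757 to 0.890) and 0.958 (0.885 to 1.04) against 0.391 (0.348 to 0.437) and 0.501 (0.45 to 0.556). Ratios above 2 were also found at the forkhead factor gene Foxd1 (2.47, 1.82 to 3.37), the adrenergic receptor gene Adrb1 (2.31, 1.84 to 2.90) and Pou4f1 (2.01, 1.66 to 2.45), although KAT7 at Pou4f1 was only 0.400 (0.357 to 0.448). The ventral forebrain factor gene Sp9 had 1.89 (1.58 to 2.27), and the cortical factor gene Emx2 had 1.41 (1.24 to 1.60). By list, 14 of 37 lay outside the random range in this ratio, 9 above and 5 below. Above were Hox genes (median log2 ratio 0.38), KAT7 complex subunits (0.25), neural stem and radial glia genes (0.24), cholesterol synthesis genes (0.24), ventral forebrain factors (0.23), Polycomb and bivalency factors (0.22), replication licensing genes (0.21), cell cycle genes (0.21) and other histone acetyltransferases (0.15). At Hox genes, KAT7 complex subunits and ventral forebrain factors, H3K14ac was below its random range and KAT7 was inside its own. Below were keratins (-0.13), endothelial and mural genes (-0.085), muscle genes (-0.070), olfactory and vomeronasal receptors (-0.045) and replication-dependent histone genes (-0.30), such as H2bc12 with 0.379 (0.212 to 0.651), H2ac19 with 0.460 (0.282 to 0.734) and H2ac21 with 0.477 (0.314 to 0.711). Histone genes exist in near-identical copies, which makes their values uncertain. In 15774 gene bodies the interval lay above 1 for 5388 and below 1 for 1429, with a median ratio of 1.05. The place of 1 depends on the column read totals, whose content is not stated. It also depends on how far each antibody enriches over background, which was not measured here.

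Around the TSS the antibodies had different profiles. In short elements centred 1 to 250 bases upstream, H3K14ac was 0.392 (0.387 to 0.397), 0.647 (0.638 to 0.655) times its level of 0.607 in elements more than 10000 bases from a TSS. KAT7 in the same elements was 0.568 (0.561 to 0.574), 0.916 (0.905 to 0.927) times its distant level of 0.620. Downstream, from 150 to 1000 bases, both were higher, by factors of 1.27 (1.26 to 1.28) for H3K14ac and 1.25 (1.24 to 1.26) for KAT7. H3K14ac was lowest between 150 and 75 bases upstream, at 0.346 (0.338 to 0.355), and highest from 250 to 400 bases downstream, at 0.848 (0.835 to 0.861). KAT7 was highest from 400 to 600 bases downstream, at 0.793 (0.782 to 0.805), and was still 0.726 (0.717 to 0.736) between 1000 and 2000 bases, where H3K14ac was 0.615 (0.606 to 0.623). At genes of the top expression class the downstream zone had 1.06 (1.03 to 1.08) for H3K14ac and 0.939 (0.914 to 0.965) for KAT7. These were 1.89 (1.76 to 2.04) and 1.61 (1.49 to 1.73) times the bottom class. Upstream, H3K14ac was 0.648 (0.575 to 0.727) times its distant level in the bottom class and 0.55 (0.518 to 0.583) times in the top class. The top class had 0.852 (0.750 to 0.972) times the H3K14ac of the bottom class, and KAT7 did not differ beyond counting error, with 1.07 (0.957 to 1.2).

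**Figure D1:**
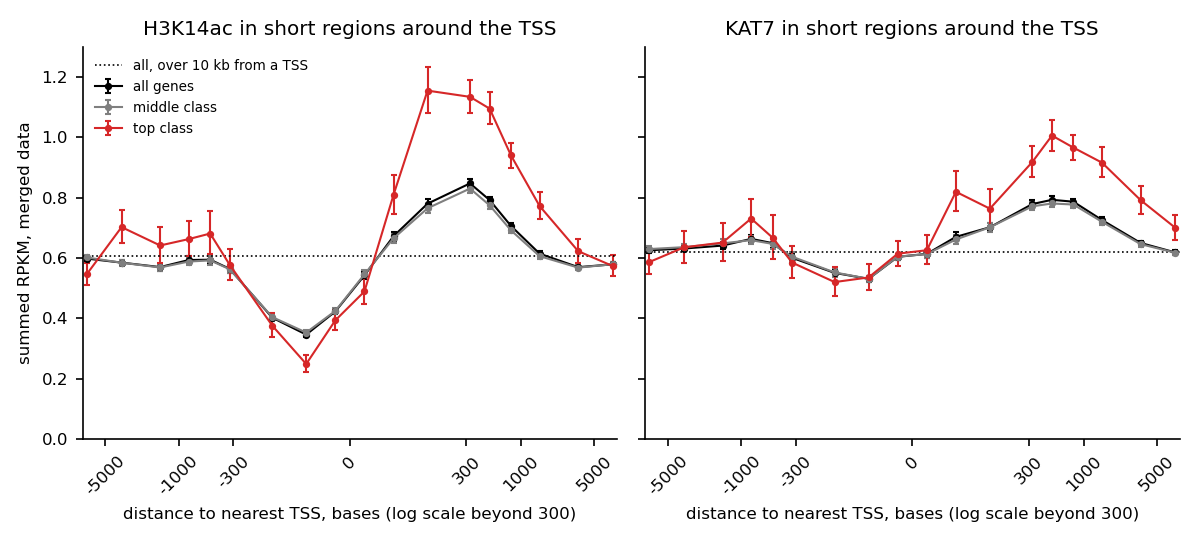
Summed RPKM of H3K14ac (left) and KAT7 (right) in short elements against distance to the nearest TSS in bases (log scale away from the TSS), for all genes, the middle and the top expression class; bars are 95% counting intervals and the dotted line is the level more than 10000 bases from a TSS. H3K14ac of all genes runs from 0.346 just upstream to 0.848 downstream, and KAT7 from 0.531 to 0.793. Enh and IS elements are pooled.

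The level at the TSS island followed the expression class for both antibodies. Islands holding a single TSS had an H3K14ac level of 0.353 (0.342 to 0.366) in the bottom class (102 islands), 0.460 (0.458 to 0.461) in the middle class (7199 islands) and 0.590 (0.584 to 0.596) in the top class (625 islands). KAT7 was 0.426 (0.413 to 0.440), 0.487 (0.486 to 0.489) and 0.573 (0.567 to 0.579). The top class was thus 1.67 (1.61 to 1.73) times the bottom class for H3K14ac and 1.34 (1.3 to 1.39) times for KAT7. In plus-strand promoter windows, which end at the TSS, the factors were 1.03 (1.02 to 1.05) and 1.1 (1.09 to 1.11). Gene bodies separated the antibodies. H3K14ac was 0.383 (0.383 to 0.384) in 876 bottom-class and 0.391 (0.390 to 0.391) in 790 top-class gene bodies, a factor of 1.02 (1.02 to 1.02), and KAT7 was 0.377 (0.376 to 0.377) and 0.429 (0.428 to 0.430), a factor of 1.14 (1.14 to 1.14). In medians of regions in place of sums, the H3K14ac factor was 1 in promoters and 1.00 in gene bodies, and at matched gene length its median over 19 bins was 0.984 (bins from 0.911 to 1.23), the opposite direction. In the window after the TES, H3K14ac of the top class was lower, at 0.921 (0.910 to 0.933) times the bottom class, and KAT7 was higher, at 1.1 (1.09 to 1.11) times.

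**Figure D2:**
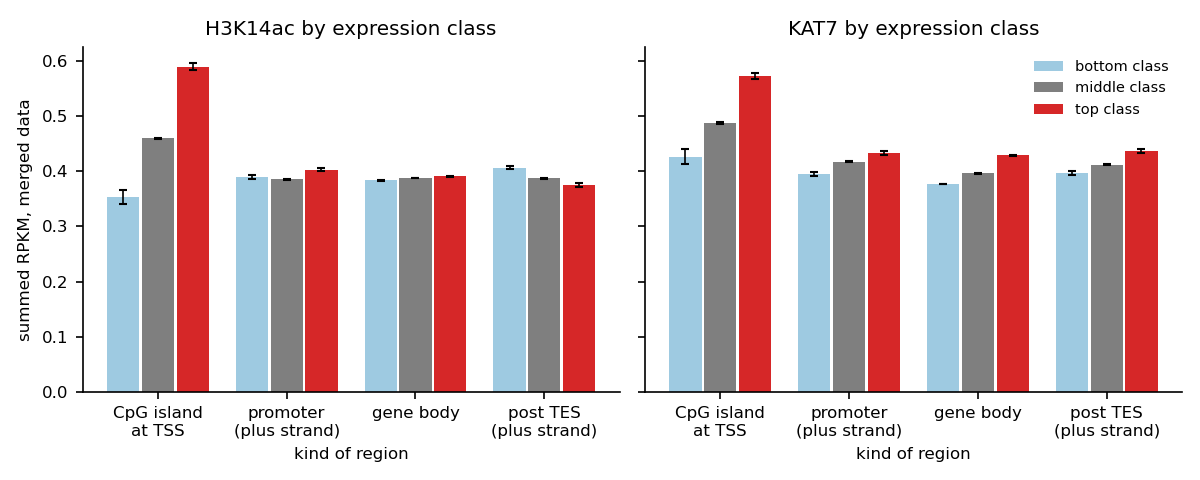
Summed RPKM of H3K14ac (left) and KAT7 (right) for genes of the bottom, middle and top expression class in TSS islands, plus-strand promoters, gene bodies and plus-strand windows after the TES; bars show 95% counting intervals. The H3K14ac bars differ most at the TSS islands, 0.353 to 0.590, and the KAT7 bars also differ in gene bodies, 0.377 to 0.429.

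Differences between classes of region depended on the band of length in which they were compared. Among regions of 701 to 1200 bases, H3K14ac was 0.469 (0.467 to 0.471) in CpG islands near a TSS, 0.428 (0.423 to 0.434) in those far from one, 0.448 (0.446 to 0.449) in Enh regions near a TSS and 0.434 (0.432 to 0.436) in Enh regions far from one, as the file names these classes. KAT7 was 0.485 (0.483 to 0.487), 0.475 (0.469 to 0.481), 0.467 (0.465 to 0.469) and 0.437 (0.435 to 0.439). In the band of 121 to 160 bases, Enh elements near a TSS had the lowest H3K14ac, 0.463 (0.459 to 0.467) against 0.581 (0.577 to 0.585) far from a TSS, and their KAT7 values were 0.617 (0.613 to 0.622) and 0.636 (0.633 to 0.640). IS elements near a TSS had the highest H3K14ac in that band, 0.622 (0.618 to 0.625). Between 251 and 400 bases H3K14ac ran from 0.433 (0.429 to 0.437) in IS elements far from a TSS to 0.6 (0.574 to 0.627) in 68 gene bodies. The file's H3K9me3 domains had medians of 0.393 and 0.392 for H3K14ac and of 0.395 and 0.392 for KAT7 in its sets 1 and 2, against 0.381 and 0.399 in gene bodies.

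**Figure D3:**
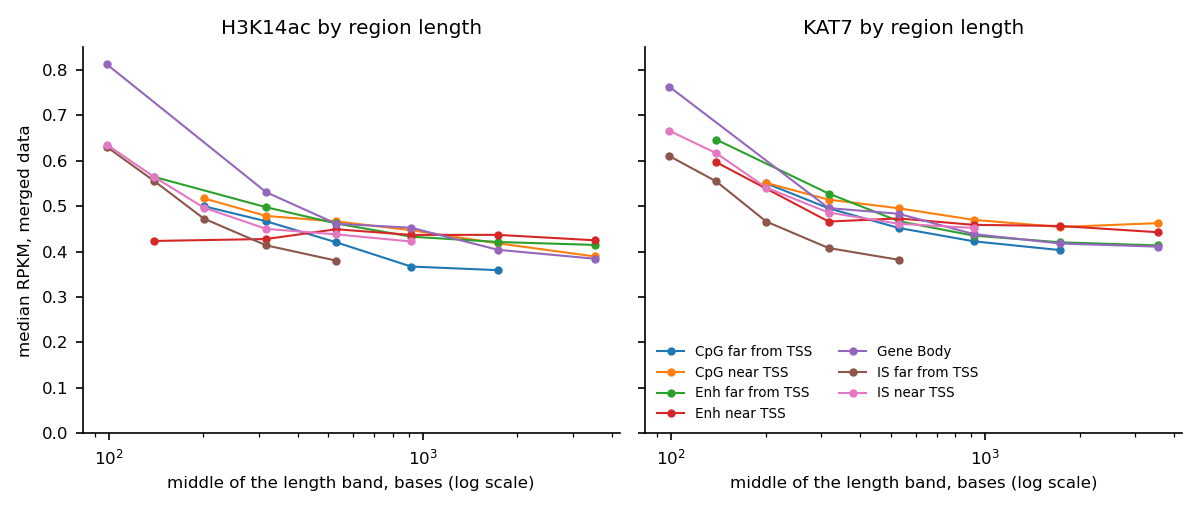
Median RPKM of H3K14ac (left) and KAT7 (right) against the middle of the length band in bases (log scale), 1 line for each class of region with at least 20 regions in a band. Gene bodies of 81 to 120 bases lie at 0.812 for H3K14ac and those of 2501 to 5000 bases at 0.384, whereas Enh regions near a TSS have their lowest H3K14ac median, 0.423, at 121 to 160 bases.

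Of the gene lists at TSS islands, the neural stem and radial glia genes (15 measured) had a KAT7 median of 0.653, above the random range of 0.417 to 0.581 (percentile 99.96), and an H3K14ac median of 0.547 inside its range. Housekeeping and glycolysis genes (15), such as Ldha with 1.16 (0.957 to 1.38) for H3K14ac, were above for both antibodies, with medians of 0.672 and 0.625, as were cytosolic ribosomal protein genes (51), with medians of 0.696 and 0.604. Replication-dependent histone genes (35) were above for H3K14ac alone, 0.614 against 0.492 for KAT7, and FGF and EGF signalling genes (12), with Spry4 and Spry2 named above, were above for H3K14ac with 0.642. Cholesterol synthesis genes (16) were below for H3K14ac with 0.320, under a range of 0.381 to 0.620. KAT7 was below at other histone acetyltransferases (8; 0.356), ventral forebrain and interneuron factors (10; 0.364), imprinted genes (10; 0.371) and Hox genes (10; 0.357, percentile 2.36). Of the 37 lists, 26 had enough members at islands, and 5 of 26 lay outside the random range for H3K14ac and 7 of 26 for KAT7. With X and Y included, KAT7 at the housekeeping and Hox lists lay inside it. Expression within the middle class was not matched, here or over gene bodies, so calls can reflect expression differences within that class. Base makeup was not matched either, so its part in the calls, including those on the ratio, is not known. The ratio of KAT7 to H3K14ac was above range for the KAT7 complex subunits (median log2 ratio 0.66) and below for histones (-0.29), ribosomal proteins (-0.19) and immediate early genes (-0.17). Genes of abundant families such as histones and ribosomal proteins have near-identical copies or pseudogenes, and reads shared with those could not be separated.

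Over gene bodies, neural stem and radial glia genes (17) were above range for both antibodies, with medians of 0.507 for KAT7 (range 0.398 to 0.439) and 0.411 for H3K14ac (range 0.367 to 0.410); Olig2 had 1.3 (1.19 to 1.41) and 0.803 (0.722 to 0.891), and Nes 0.850 (0.8 to 0.903) and 0.851 (0.802 to 0.902). Ribosomal protein genes (35; H3K14ac 0.525, KAT7 0.544), housekeeping genes (12; 0.424, 0.509), histones (54; 0.744, 0.558) and cell cycle inhibitors with p53 targets (17; 0.405, 0.451) were also above for both. Of the last, Cdkn1b, a cyclin-dependent kinase inhibitor gene, had 0.658 (0.599 to 0.721) for KAT7 and 0.432 (0.386 to 0.483) for H3K14ac. KAT7 alone was above at Notch pathway genes (15; 0.433), where Hes1, a Notch effector, had 0.697 (0.609 to 0.794), and at Polycomb and bivalency factors (18; 0.418). H3K14ac was below at Hox genes (18; 0.309), imprinted genes (14; 0.324), mesoderm and endoderm regulators (19; 0.333), KAT7 complex subunits (9; 0.343) and ventral forebrain factors (15; 0.349). KAT7 was below at keratins (40; 0.343), imprinted genes (0.357), endothelial and mural genes (15; 0.364) and oligodendrocyte lineage genes (12; 0.373), although Olig1 in that list had 1.21 (1.08 to 1.34). In all, 12 of 37 lists were outside for H3K14ac and 11 of 37 for KAT7. Some calls ended under an alternative: H3K14ac at neural stem genes with X and Y included or with length matched in 5 bins, H3K14ac at cell cycle inhibitors with 5 bins, and KAT7 at oligodendrocyte genes with X and Y included or without a minimum. Markers of other cell types were inside the range for both antibodies for astrocytes (12; 0.388, 0.389), microglia (9; 0.390, 0.374), erythroid cells (5; 0.358, 0.371), meningeal fibroblasts (10; 0.371, 0.395), liver (8; 0.381, 0.391) and muscle (9; 0.400, 0.376).

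**Figure D4:**
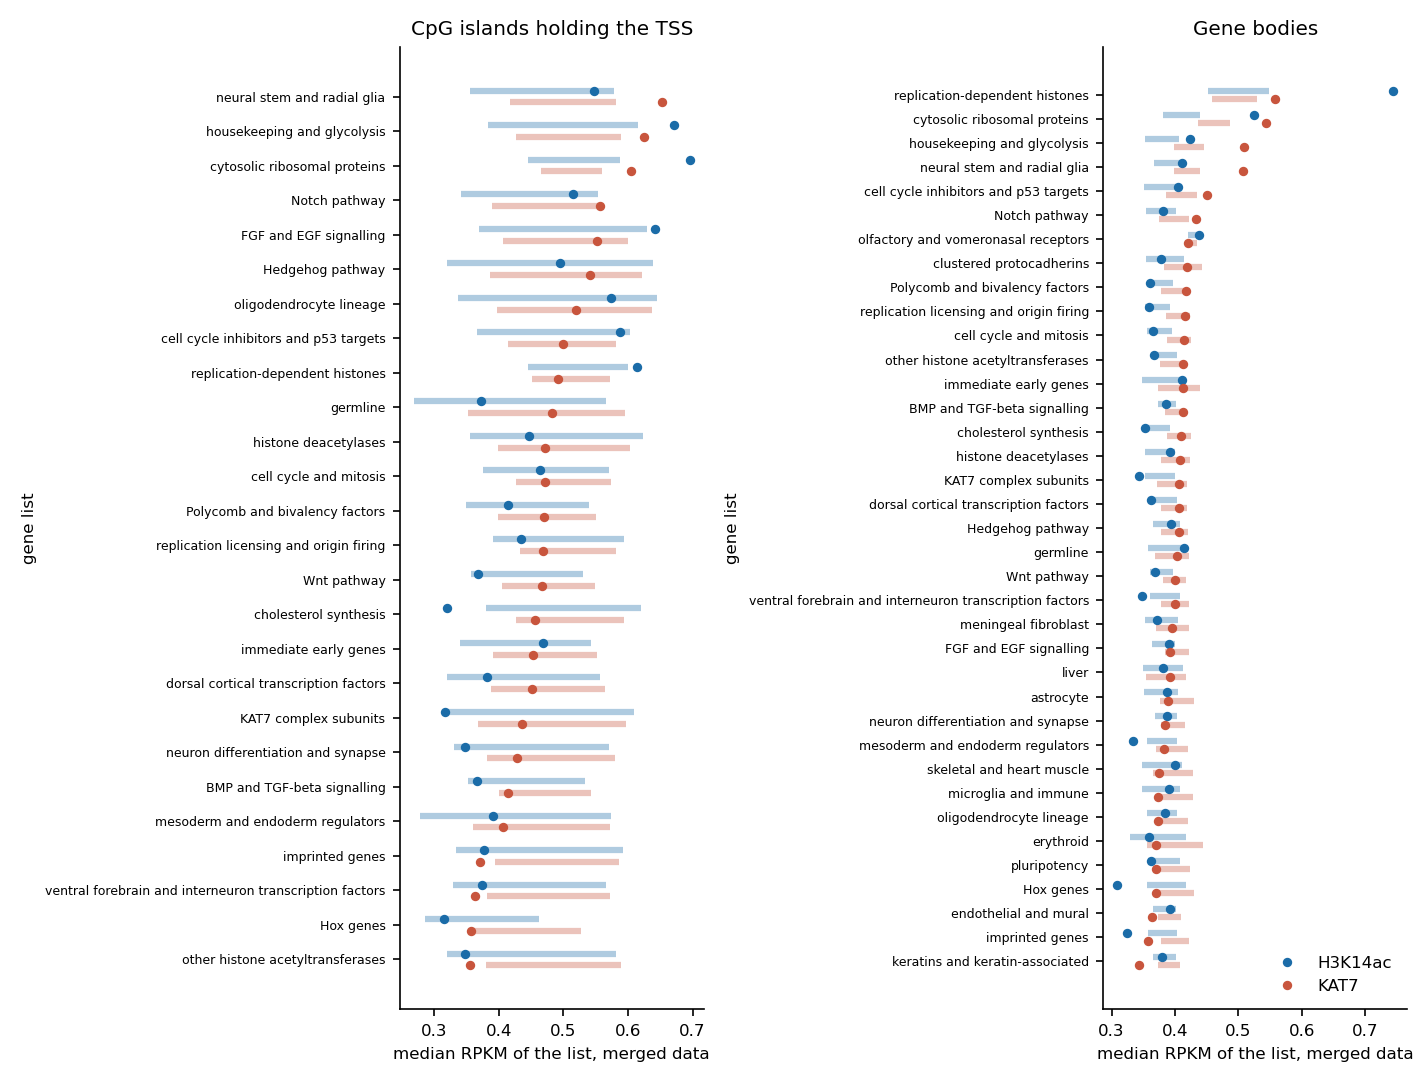
Median RPKM of each gene list for H3K14ac (blue) and KAT7 (red) at CpG islands holding the TSS (left) and over gene bodies (right), with the central 95% of 10000 matched random lists as a bar behind each point. Neural stem and radial glia genes lie at 0.653 for KAT7 at islands and 0.507 over gene bodies, right of their bars.

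The lists not yet described lay inside the random range for both antibodies over gene bodies except germline genes (9) and olfactory and vomeronasal receptors (384), whose H3K14ac medians of 0.414 and 0.438 were above it. Under alternatives some lists inside the range lay outside it. With X and Y included, H3K14ac was below at neuron differentiation genes, also at islands, and KAT7 at erythroid genes. Without a minimum, KAT7 was below at FGF and EGF genes and at Hox genes over gene bodies, and above at Notch genes at islands. With 5 length bins, KAT7 was above at olfactory receptors and, at islands, Notch genes, and H3K14ac was below at Polycomb factors over gene bodies. Dorsal cortical factors (18) had medians of 0.363 for H3K14ac and 0.406 for KAT7, neuron differentiation and synapse genes (14) 0.387 and 0.385, pluripotency genes (10) 0.362 and 0.370, replication licensing genes (19) 0.359 and 0.415, and cell cycle genes (18) 0.365 and 0.414. Wnt pathway genes (20) had 0.368 and 0.401, Hedgehog genes (9) 0.393 and 0.406, BMP and TGF-beta genes (23) 0.386 and 0.412, and FGF and EGF genes (16) 0.391 and 0.393. Other histone acetyltransferases (10) had 0.367 and 0.413, histone deacetylases (11) 0.392 and 0.408, cholesterol genes (17) 0.353 and 0.409, immediate early genes (15) 0.411 and 0.413, and protocadherins (22) 0.378 and 0.419. Dcx and Tubb3, markers of young neurons, had gene body KAT7 values of 0.193 (0.185 to 0.202) on chromosome X and 0.348 (0.317 to 0.380) on chromosome 8. Gfap, the astrocyte filament gene, had 0.388 (0.355 to 0.423), and the replication helicase gene Mcm2 had 0.400 (0.373 to 0.428).

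KAT7 and H3K14ac were related across regions in every class. Spearman's rho was 0.45 across 7926 TSS islands, 0.366 across 9809 plus-strand promoters and 0.385 across 15774 gene bodies. Counts simulated with no difference between regions gave 0.037, -0.0011 and 0.028. The simulation held no bias of sequence, copy number or background that both columns could share. The rho values therefore do not show whether KAT7 follows H3K14ac. In the other classes rho lay between 0.255 in post-TES windows and 0.472 in the H3K9me3 domains of set 2. In Enh regions far from a TSS the simulation alone gave 0.343, of 0.414 observed. Regions are not independent replicates, so no test was made. With only regions of at least 0.5 RPKM in the mean of both columns, rho was -0.132 at islands and 0.0123 at promoters, a filter that selects on both values at once.

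Gene bodies on chromosome X had a median of 0.528 times the autosomal one for H3K14ac and 0.523 times for KAT7, and those on Y had 0.534 and 0.557 times. The 19 autosomes lay between 0.971 and 1.02 for H3K14ac and between 0.980 and 1.03 for KAT7. All comparisons above were therefore made on autosomes, other than the values of genes named on X and the alternatives with X and Y included.

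**Figure D5:**
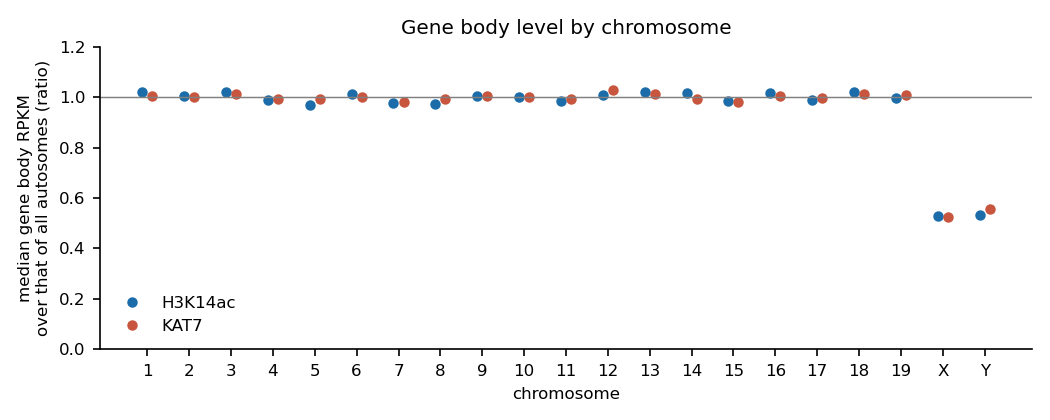
Median gene body RPKM of each chromosome divided by that of all autosomes, for H3K14ac (blue) and KAT7 (red). X lies at 0.528 and 0.523 and Y at 0.534 and 0.557, while the autosomes lie between 0.971 and 1.03.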

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

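Of the tests given here, the ratio of X to autosomes as a test of copy number was chosen after the result was seen, and the test of repeated sequence on X was written before. Each result below stands out as signal in regions that the comparisons do not use.

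Gene bodies on chromosome X had 0.528 times the autosomal median for H3K14ac and 0.523 times for KAT7, and those on Y had 0.534 and 0.557 times; over the classes of region the X ratios lay between 0.464 and 0.677. Loss of reads from a repeated part of X was argued against as the whole cause, since 99.7% of 393 X gene bodies over 10 kb lay below the autosomal 10th percentile of 0.335 for H3K14ac. A single copy of X and of Y per cell stays open as a candidate explanation. The ratio of 0.528 lies near what it predicts, but that ratio is also the observation, so it adds no separate support. The labels used here do not give the sex of the embryos, and no other biological explanation was tested.

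The 8 mitochondrial gene bodies that share no bases with another had 9.15 (8.97 to 9.33) RPKM for KAT7 and 1.09 (1.03 to 1.15) for H3K14ac, a ratio of 8.43 (7.95 to 8.95) that ranged from 6.34 to 10.2 between genes. In 370 regions outside the mitochondrial genome a value exceeded 5 RPKM, up to 249.8 for H3K14ac and 239.9 for KAT7. Of these, 234 were IS elements far from a TSS, 115 lay on chromosome 11 and 72 on chromosome 9, and the columns ranked the regions alike (Spearman's rho 0.976 across regions).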

How the results depend on the processing

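The minimum RPKM for the rank correlation was varied as set before the data were examined, and all other alternatives were added after seeing the data. For 17 results, 71 alternative values were computed: 36 stayed within the interval of the value reported (counts of lists, within 1.5 times), 34 lay outside it without reversing (1 of them at exactly 1) and 1 reversed. With only regions of at least 0.5 RPKM, the rank correlation was -0.132 at TSS islands, the value that reversed, 0.0123 at promoters and 0.258 in gene bodies; selecting on the mean of both values lowers a correlation by construction. Without a minimum it was 0.402 in gene bodies, and the upstream to distant ratios were 0.630 for H3K14ac and 0.896 for KAT7. With X and Y included, the correlations were 0.477 at islands, 0.433 at promoters and 0.454 in gene bodies, and the KAT7 gene body factor between the top and bottom class was 1.14. Medians of regions gave factors of 1.5 for H3K14ac and 1.22 for KAT7 at islands, 1 for H3K14ac at promoters, 1.00 and 1.16 in gene bodies, and distant ratios of 0.56 upstream for H3K14ac and of 1.2 and 1.22 downstream. The small H3K14ac differences at promoters and gene bodies were thus not seen in medians. With overlapping regions included, the KAT7 promoter factor was 1.08 and the gene body factors were 1.03 and 1.15. Islands of over 400 and up to 700 bases gave 1.46 and 1.22. Upstream and downstream, H3K14ac had 0.585 and 1.03 and KAT7 0.873 and 1.1 in Enh elements, 0.748 and 1.29 against 0.953 and 1.28 in IS elements, and 0.709 and 1.17 against 0.948 and 1.21 outside CpG islands. Counts of lists outside the random range stayed within 1.5 times, but with X and Y included 5 of the 7 KAT7 calls at islands were shared. No alternative was run for the list calls on the KAT7 to H3K14ac ratio. The cause was not tested for any of these.

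No paired analysis was possible because the merged columns carry no replicate numbers. For want of values per library, no alternative set beforehand for the genotype and IgG comparisons was run: pseudocount, minimum, scaling, variance trend, shared fits, array weights, IgG subtraction, fold threshold, set-test method, replicate block and leaving out each replicate. The last was not run for the rank correlation either, which a pseudocount cannot alter. Depth limits single short regions: the median H3K14ac count was 11 in IS elements far from a TSS and 40 in islands with 1 TSS, and in simulated islands a true ratio of 1.5 was told from 1 in 59.7%.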

Other observations

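The tests of base makeup, of sequence that takes few reads, of nucleosomes and of gene length were chosen after the result was seen, and those of long genes and of neighbouring genes were written before. The genes and elements in the next 2 paragraphs were chosen after their values were seen.

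Few long gene bodies stood above the general level for both antibodies. Of 10294 autosomal gene bodies over 10 kb, 36 had more than 0.55 RPKM in both columns, and 13 of these lay in a cluster of mostly zinc-finger genes on chromosome 4 (145670697 to 147809788), with medians of 0.953 for H3K14ac and 0.964 for KAT7. In it, Zfp992 had 1.29 (1.25 to 1.33) and 1.41 (1.37 to 1.46), Zfp980 1.2 (1.17 to 1.23) and 1.22 (1.19 to 1.25), and Rex2 0.990 and 1.05. Zinc-finger genes of such clusters have near-identical copies, and shared reads could not be separated. Smo, which encodes the Hedgehog signal transducer smoothened (chromosome 6, 29735497 to 29761366), had 0.925 for H3K14ac and 0.871 for KAT7. Its reads lay mostly in an entry of the H3K9me3 domains inside the gene (29742310 to 29754310), with 1.55 and 1.38, against 0.303 and 0.358 in its promoter, and whether that stretch has further copies was not checked. Spry4 (chromosome 18, 38586265 to 38601268) was also among the 36, with 0.639 (0.605 to 0.674) and 0.728 (0.691 to 0.766). Duxf3, a member of a multi-copy homeobox family (chromosome 10, 58229979 to 58232873), had the highest values of the gene bodies named, 4.61 (4.40 to 4.82) and 4.46 (4.25 to 4.68).

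At Nes the antibodies differed over a short distance. An IS element just upstream of the TSS (chromosome 3, 87970950 to 87971087) held 33 H3K14ac and 92 KAT7 reads, or 1.70 and 5.01 RPKM, which puts it among the 370 regions above 5 RPKM that were set apart. The next IS element, inside the gene (87971536 to 87971699), had the opposite order, with 80 and 35 reads, or 3.46 and 1.60 RPKM. The other IS elements inside the gene held 53 and 53, 20 and 32, 18 and 20, and 18 and 13 reads. Reads from the nestin-driven transgene could not be separated where its sequence is shared.

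H3K14ac just upstream of the TSS was 0.647 times its distant level, and KAT7 0.916 times. The base makeup of CpG islands was argued against as the whole cause, because outside islands the H3K14ac ratio was 0.709 (0.694 to 0.724). Sequence that takes few reads to the same degree in both columns was argued against as the whole cause. In that case KAT7 relative to H3K14ac upstream would match its distant value, but it was 1.42 (1.39 to 1.44) times that value. Fewer nucleosomes upstream of active genes were argued against as the whole cause, because the ratio was 0.648 (0.575 to 0.727; 39 elements) in the bottom expression class as well, although it was lower, 0.55 (0.518 to 0.583), in the top class. A correction of the alignments before counting and fewer nucleosomes upstream of genes of any class stay open. So does sequence that takes few reads, as part of the cause or to an unequal degree between the columns. IgG and total H3 were not analysed here, and no biological explanation from the genotypes was tested.

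KAT7 over gene bodies was 1.14 times as high in the top as in the bottom expression class, against 1.02 times for H3K14ac, which at matched length was 0.984 (bins from 0.911 to 1.23). Shorter genes in the top class were argued against as the whole cause, since at matched length the median ratio over 19 bins was 1.14 (bins from 1.1 to 1.35), and so was KAT7 near the TSS alone, since gene bodies over 30 kb (165 top, 311 bottom) had 1.13 (1.12 to 1.13), against 1.03 (1.03 to 1.03) for H3K14ac. Parts of the genome that take more KAT7 reads could account for some of it: middle-class genes within 100 kb of top genes (664) had 1.05 (1.04 to 1.06) times the KAT7 median of those near bottom genes (614), 32.0% (23.4 to 41.5) of the excess in medians of the genes themselves. This share lies between the bounds set beforehand for and against that source, so a regional source and one bound to the genes cannot be told apart. No biological explanation from the genotypes was tested.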
